A study of Mus musculus with 18 samples.

How the data were processed

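RNA of 18 mouse intestine samples, in 6 groups of 3, was measured on 18 two-colour Agilent arrays of 45018 spots, of which 1639 were control spots. Per the labels, sample RNA was labelled with Cy5 (red) and a commercial pool of Swiss Webster mouse RNA with Cy3 (green), by indirect labelling of cDNA. The pool held RNA of embryos and of 9 adult organs, liver and spleen among them, and no intestine, and dyes were not swapped. Groups were taken from the labels. The labels call the tissue small intestine, while their extraction protocol names liver; the tissue is described here as intestine.

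Per the file headers, arrays were scanned and read with Agilent Feature Extraction 10.10.1.1 and protocol GE2_1010_Sep10, and the array annotation is on mouse build mm9. The deposited intensity values are the median pixel intensity of each spot and of its local background in each channel. The deposited log10 ratio, per the file headers, is red over green after the software's background subtraction and dye normalization. The deposited log2 values form a table that holds 35491 entries. It matched the log2 of red over green processed signals of the scanner files on each array (slope 1 to 1.003, r of at least 0.9955), so its scale and direction are settled. Its columns were not centred on their medians, and the reason for its selection of probes is not given in the sources used here. Their medians for replicates 1 to 3 were 0.159, 0.207 and 0.15 (control saline), 0.226, 0.146 and 0.146 (SJW saline), 0.102, 0.205 and 0.053 (control AOM), 0.109, 0.129 and -0.032 (SJW AOM), 0.158, 0.126 and 0.342 (control tumour) and 0.183, 0.125 and 0.157 (SJW tumour).

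The mean spot intensity was planned as input but is not among the columns used here, and the median spot intensity took its place. Background was corrected with normexp and an offset of 50, and log2 ratios were normalized within each array by loess with control spots at weight 0. Control spots and spots that the software marked as population outliers (0.27% to 0.505% of spots) were left out. Spots marked as non-uniform (7.89% to 28.1%) were kept, since they made up 25.1% to 76.1% of spots in the brightest of 5 equal classes and 0.3% to 2.5% in the dimmest. Spots of one probe were averaged. A probe was kept if well above background in red on all 3 arrays of any group, which left 34081 of 41174 probes. Of these 41174, 27050 had 1 gene symbol through their RefSeq accession, 14124 had none and 0 matched several. Names came from a RefSeq table of assembly GRCm38.p6, used only for names and not for coordinates. Of several kept probes of a gene (6158 genes) the brightest on average was used. This gave 26073 genes, 9274 of them without a symbol.

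Red signal over background was 2.08 to 5.91 on non-tumour and 5.28 to 12.1 on tumour arrays, and the number of arrays limits the precision. Correlation of log2 ratios was 0.903 to 0.958 within groups and 0.692 to 0.975 between groups. Slides and scan days are recorded in the files. The 12 non-tumour arrays lay on 3 slides with 1 array of each group on each, scanned on day 1; the 6 tumour arrays lay on 2 slides, scanned on day 2. With slide as a term, 38 genes differed between the non-tumour slides and 6 between the tumour slides.

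Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, files read with the data.table package, version 1.17.8), in 1 fit of all 18 arrays with 12 residual degrees of freedom. There were 10 comparisons: AOM against saline in each diet, tumour against non-tumour tissue in each diet, SJW against control after saline, after AOM and in tumours, the average of these last 3, and the differences of the AOM and tumour changes between the diets. P-values were adjusted within each comparison by Benjamini and Hochberg, with a threshold of 0.05. Of 35 gene lists, 34 with at least 5 measured genes were tested with camera at a preset correlation of 0.01, adjusted over the lists; the erythroid list was too small. They covered 13 pathways (xenobiotic metabolism, NF-kB, ERK, Wnt, proliferation, p53, NRF2, fatty acid oxidation, cholesterol biosynthesis, interferon, MHC class II, circadian clock, heat shock) and 22 tissues or cell types. Comparisons, lists, tests and the other settings to try were fixed before the data were examined.

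Named genes followed a fixed rule. Per comparison these were the 8 largest changes up and the 8 down among genes that passed and whose groups did not overlap, without accession, RIKEN, Gm or LOC names. To these were added the 3 members with the smallest p of each called list in its direction, and 13 genes named for every comparison, of which 12 were measured and Ccnd1 was not analysed here. With fewer than 10 called genes, the 5 up and 5 down with the smallest p were added. The text leaves out some of them, and a few are not reported here, nor counted among the named genes in the comparison of settings. A gene not well above background on any array of 1 group was given as a bound, the bright group's mean against the higher of the dim signal and the lowest signal well above background on each array, per channel after loess and Aquantile.

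Replicate numbers are shared between groups. Same-numbered non-tumour arrays share a slide, per the file headers. In the SJW comparison after saline the deviations of same-numbered arrays from their group means correlated at 0.169 to 0.41 in 3 of 3 pairs, and 0 genes passed with or without the replicate number as a block.

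Simulated changes added for the AOM comparison on the control diet, over 26073 genes, were recovered in 59% of cases at a log2 change of 1 and 88% at 2, all with the right sign. Of the genes called there, 8 were unchanged ones (4.5%). All 10 changed lists and 0 of 20 unchanged lists were called, with the preset and with an estimated correlation. These lists were of random genes, with noise drawn independently for each gene. The simulation therefore cannot show how the list test does where members of a list are correlated. Alternatives were the software's own log ratio centred on its median, median centring in place of loess, Aquantile, the red channel alone with quantile normalization, the deposited log2 values, no filter, a filter on both channels, the mean of probes, array weights, a trended and robust variance, only the groups compared, slide or replicate number as a block, each array left out, camera with an estimated correlation, and fry. Added after the data were seen were leaving out non-uniform spots, the brightness of the reference channel as a block, leaving out the 6 arrays of bright reference (median green intensity 507 to 755, against 198 to 298), and slide as a block for lists.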

Results

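Gene expression was measured in the intestine of male C57BL/6 mice that ate a control diet or a diet with St. John's wort (SJW), a medicinal herb, and were injected with saline or with azoxymethane (AOM), a carcinogen used to induce intestinal tumours in rodents. There were 6 groups of 3 arrays: non-tumour tissue of each diet after saline, non-tumour tissue of each diet after AOM, and tumours of each diet after AOM. Each of the 18 arrays set the RNA of 1 sample, in red, against the same commercial pool of mouse RNA, in green. A positive log2 ratio means more transcript in the sample than in the pool. The labels describe the tissue as small intestine, while the extraction protocol names liver. The median red intensity was 133 to 375 on non-tumour arrays and 336.5 to 786.5 on tumour arrays. Over all arrays 66.0% to 91.8% of probes were well above background in red. Log2 ratios of 26073 genes were compared, 16799 of them with a gene symbol. Changes are log2 differences ± SE, with 3 arrays in each group, and the number of arrays limits their precision. The series design calls the arrays biological replicates.

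The first comparison asked what AOM did in non-tumour tissue on the control diet. Defa23 and Defa22, which encode antimicrobial alpha-defensins of Paneth cells, were higher after AOM, by 4.15 ± 0.57 (17.7-fold) and 3.11 ± 0.48. Their sequences are closely related, so the values are uncertain as those of single genes. Over both diets Defa23 was well above background on 3 of 6 saline arrays, so the size of its change is also uncertain. Wfdc18 rose by 4.03 ± 0.55, the secreted Wnt inhibitor Wif1 by 2.82 ± 0.58, the BMP antagonist Grem1 by 2.76 ± 0.54, the cornified envelope gene Sprr1a by 2.38 ± 0.30 and the growth factor binding protein gene Igfbp5 by 2.25 ± 0.24. Slc37a2, a sugar phosphate transporter gene, fell by 2.15 ± 0.29, and Kyat1 fell by 1.37 ± 0.27. The clock-controlled transcription factor gene Dbp fell by 0.91 ± 0.19.

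In all, 151 genes passed the test, 119 higher and 32 lower after AOM, with adjusted p of 0.00592 for Defa23 and 0.00586 for Slc37a2. Their median size was 0.70 to 1.09 within each of the 3 slides, on genes chosen from these same arrays. With slide as a block 143 genes passed, 106 of them among the 151. With that block the adjusted p was 0.0552 for Wif1, 0.0734 for Egr1 and 0.055 for Plk1, all 3 of which passed without it. Of the 12 genes reported in every comparison (Cyp3a11, Il6, Il1b, Tnf, Ptgs2, Nos2, Lcn2, Myc, Axin2, Lgr5, Mki67 and Fos), 0 passed.

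Smooth muscle genes were higher as a group after AOM: all 13 members had positive changes, with a median of 2.09 (adjusted p = 0.208 with an estimated correlation). Over all genes 0 of the 13 passed, and 13 were higher when adjusted over the list alone. Cald1 was at 2.09 ± 0.51, Myl9 at 2.24 ± 0.59 and the smooth muscle actin gene Acta2 at 0.86 ± 0.24. The median of this list ranged from 0.12 to 3.62 within slides. All 20 fibroblast and extracellular matrix genes had positive changes (median 1.04; 0 called, 13 adjusted over the list alone; adjusted p = 0.0558 with an estimated correlation), with Dcn at 1.43 ± 0.31. Mast cell markers had a median change of 0.96, with 8 of 9 members positive and 0 passing, over all genes or adjusted over the list alone (adjusted p = 0.418 with an estimated correlation). The mast cell median was 0.35 without control AOM replicate 2 and 0.21 to 1.94 within slides.

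Proliferation genes were higher in 27 of 28 members after AOM, with a median of 0.52 (adjusted p = 0.0558 with an estimated correlation). Cdc20 rose by 0.84 ± 0.15 and Plk1 rose by 0.65 ± 0.14, both mitotic regulators; 2 members passed over all genes and 17 adjusted over the list alone. Of 26 Wnt and beta-catenin targets, 23 were positive and 3 passed (9 adjusted over the list alone; adjusted p = 0.0694 with an estimated correlation), among them Nkd1 at 1.97 ± 0.29 and Cd44 at 1.49 ± 0.31. ERK and immediate early targets included 3 called genes of 25 (8 adjusted over the list alone), Phlda1 at 1.40 ± 0.17, Dusp6 at 0.93 ± 0.16 and Egr1 at 1.08 ± 0.23. Their mean was 0.575 in control AOM replicate 2, against 0.24 and 0.27 in the other replicates, and that of heat shock and handling stress genes was 0.92 there, against 0.055 and -0.13. Without that array the heat shock median went from 0.48 to 0.32 (adjusted p = 0.0925), and the ERK median from 0.34 to 0.19. Of 15 circadian clock genes, 12 were lower; Dbp passed, and 5 passed adjusted over the list alone. Adjusted p was 0.0471 for ERK targets and 0.0448 for clock genes with an estimated correlation. These 2 lists were the only calls of this comparison that held.

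Set tests called 20 of 34 lists after AOM on the control diet, 15 higher and 5 lower. Besides those above, lists of NRF2 and antioxidant, p53 and DNA damage, NF-kB, cholesterol biosynthesis, heat shock, Paneth cell, enteroendocrine, macrophage and endothelial genes were higher, with medians of 0.43, 0.18, 0.08, 0.36, 0.48, 0.50, 0.35, 0.34 and 0.29. Gpx2, an antioxidant enzyme gene, rose by 1.34 ± 0.29, and Phlda3, a p53 target, rose by 1.73 ± 0.25. Their lists had 5 higher and 1 lower member (NRF2) and 3 higher members (p53) adjusted over the list alone. Xenobiotic metabolism, ileum, colon and adipocyte lists were lower, with medians of -0.12, -0.47, -0.35 and -0.27. Adjusted p of the lists of this paragraph was 0.0558 for NRF2 and 0.309 for Paneth cell genes with an estimated correlation, and 0.418 to 0.443 for the others. Of the 20 medians 4 turned between slides: endothelial (-0.33 to 0.73), NF-kB (-0.085 to 0.19), ileum (-0.43 to 0.18) and colon (-0.59 to 0.03). All 20 calls held with slide as a block and 17 with the brightness of the reference, described next, as a block, with adjusted p of 0.0871 for colon, 0.0768 for enteroendocrine and 0.0511 for macrophage genes. Leaving out 1 array ended the call or moved the median by over 1.5 times for 14 of the 20 lists. Without control AOM replicate 2 the medians of Paneth cell, NF-kB, adipocyte and xenobiotic genes were 0.24, 0.02, -0.04 and -0.03. Without control saline replicate 3, 13 lists were called.

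The count of genes depended on single arrays. It was 11 without control saline replicate 1, 27 without replicate 2 of that group, 46 without control AOM replicate 1 and 28 without replicate 2 of that group. With each array centred on its median in place of loess, 275 genes were higher and 5 lower, and with the red channel alone 110 and 55. The scanner's own log ratio gave 352 and 212, and the deposited values gave 213 and 122. Of the 151 genes, 106 also passed with median centring and 76 with the red channel alone. With the scanner's own log ratio 117 of the 151 passed, and with the deposited values 65. Of the 18 arrays, 6 had a brighter reference channel than the rest, 4 of them after saline; 267 genes passed with that brightness as a block. Without those 6 arrays 0 passed, with 1 saline array left on each diet, and the adipocyte median was 0.12.

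The same comparison on the SJW diet gave 295 genes, 171 higher and 124 lower after AOM. Defa23 rose by 3.34 ± 0.57 and Defa22 by 2.22 ± 0.48, and the chaperone gene Clu rose by 2.30 ± 0.39. Cd74, the invariant chain of MHC class II, rose by 1.93 ± 0.31, and the matrix genes Ccn2 and Col1a1 rose by 2.21 ± 0.50 and 1.94 ± 0.43, with the muscle actin gene Acta1 at 2.08 ± 0.40. Lower genes included Ces2a, a carboxylesterase gene, at -2.61 ± 0.53, Slc37a2 at -2.29 ± 0.29, Hsd17b13 at -2.16 ± 0.48 and Ugt1a1, which encodes a glucuronosyltransferase, at -2.15 ± 0.50. Abcb1b and Abcb1a, the drug efflux pump genes, fell by 2.13 ± 0.32 and 2.05 ± 0.29, and Cyp2c55, a cytochrome P450 gene, fell by 2.06 ± 0.48.

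Xenobiotic metabolism genes were lower in 30 of 34 members, with a median of -0.73; 7 fell over all genes and 18 adjusted over the list alone (adjusted p = 0.15 with an estimated correlation). MHC class II genes were higher in all 7 members, with a median of 1.24; 4 passed over all genes and 7 adjusted over the list alone, H2-Ab1 at 1.67 ± 0.33 and H2-Aa at 1.84 ± 0.37 (adjusted p = 0.157 for the list with an estimated correlation). Of 20 matrix genes 7 rose (16 higher and 1 lower adjusted over the list alone), Col5a1 by 1.52 ± 0.28 and Dcn by 1.63 ± 0.31 (adjusted p = 0.15 for the list with an estimated correlation). All 13 smooth muscle genes were positive, with a median of 1.90, 0 called and 12 adjusted over the list alone (adjusted p = 0.279 with an estimated correlation). Macrophage genes Lyz2, C1qc and C1qa rose by 1.84 ± 0.39, 1.34 ± 0.30 and 1.32 ± 0.30 (8 of 14 adjusted over the list alone; adjusted p = 0.215 for the list with an estimated correlation). Macrophage genes had a mean of 0.64 in SJW AOM replicate 3, against -0.12 and -0.003 in the other replicates, and MHC class II genes 0.965, against 0.27 and -0.12. Pancreatic acinar genes were at 3.49 in that array, without which the macrophage median went from 0.63 to 0.41.

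Fatty acid oxidation genes fell in 3 of 18 members (8 adjusted over the list alone; adjusted p = 0.212 with an estimated correlation), with Slc25a20 at -1.05 ± 0.18 and Hadha at -0.62 ± 0.13. ERK targets Dusp6, Egr1 and Phlda1 rose by 0.82 ± 0.16, 1.11 ± 0.23 and 0.73 ± 0.17 (6 of 25 adjusted over the list alone; adjusted p = 0.162 with an estimated correlation). With slide as a block the adjusted p was 0.052 for both Hadha and Phlda1. Of 34 lists 20 were called, 13 higher and 7 lower. They also held proliferation, Wnt, interferon, heat shock, T cell, B and plasma cell, endothelial and enteric neuron lists, which were higher at medians of 0.28, 0.28, 0.59, 0.39, 0.49, 0.48, 0.36 and 0.32. Goblet cell, enterocyte, ileum, colon and adipocyte lists were lower at medians of -0.53, -0.30, -0.79, -0.51 and -0.73. The interferon median was -0.52 to 1.07 within slides and 0.05 without SJW saline replicate 1. Leaving out 1 array ended the call or moved the median by over 1.5 times for 10 of the 20 lists, with endothelial genes at 0.16 without SJW AOM replicate 3 and heat shock genes at 0.20 without replicate 2. With an estimated correlation 0 calls held, at adjusted p of 0.15 to 0.526.

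The median size of the 295 genes, chosen from these same arrays, was 0.85 to 1.20 within each of the 3 slides, and 432 passed with slide as a block. The count was 0 without SJW saline replicate 3 or without SJW AOM replicate 2, 5 without SJW AOM replicate 3, 180 without SJW saline replicate 1 and 600 without replicate 2 of that group. It was 7 with reference brightness as a block, 0 without the 6 arrays of bright reference (1 SJW saline array left), 8 with the red channel alone (4 higher, 4 lower), 66 with the deposited value table and 116 with the scanner's own log ratio. Median centring gave 113 higher and 26 lower genes.

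The AOM comparisons of the 2 diets share no arrays, but they share the slides and 1 fit, so their lists are not independent. They shared 45 higher genes, where independent lists would share 0.8, and 5 lower genes against 0.2, with 0 called in opposite directions. The test of the difference between the diets called 0 genes by limma (2438, or 9.4%, at an unadjusted p under 0.05). In that test Cd74 was at 2.04 ± 0.43, H2-Aa at 2.20 ± 0.52 and Akr1b8, an aldo-keto reductase gene, at -1.36 ± 0.23 (adjusted p = 0.475 for each). It called 2 genes without control saline replicate 3.

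**Figure D1:**
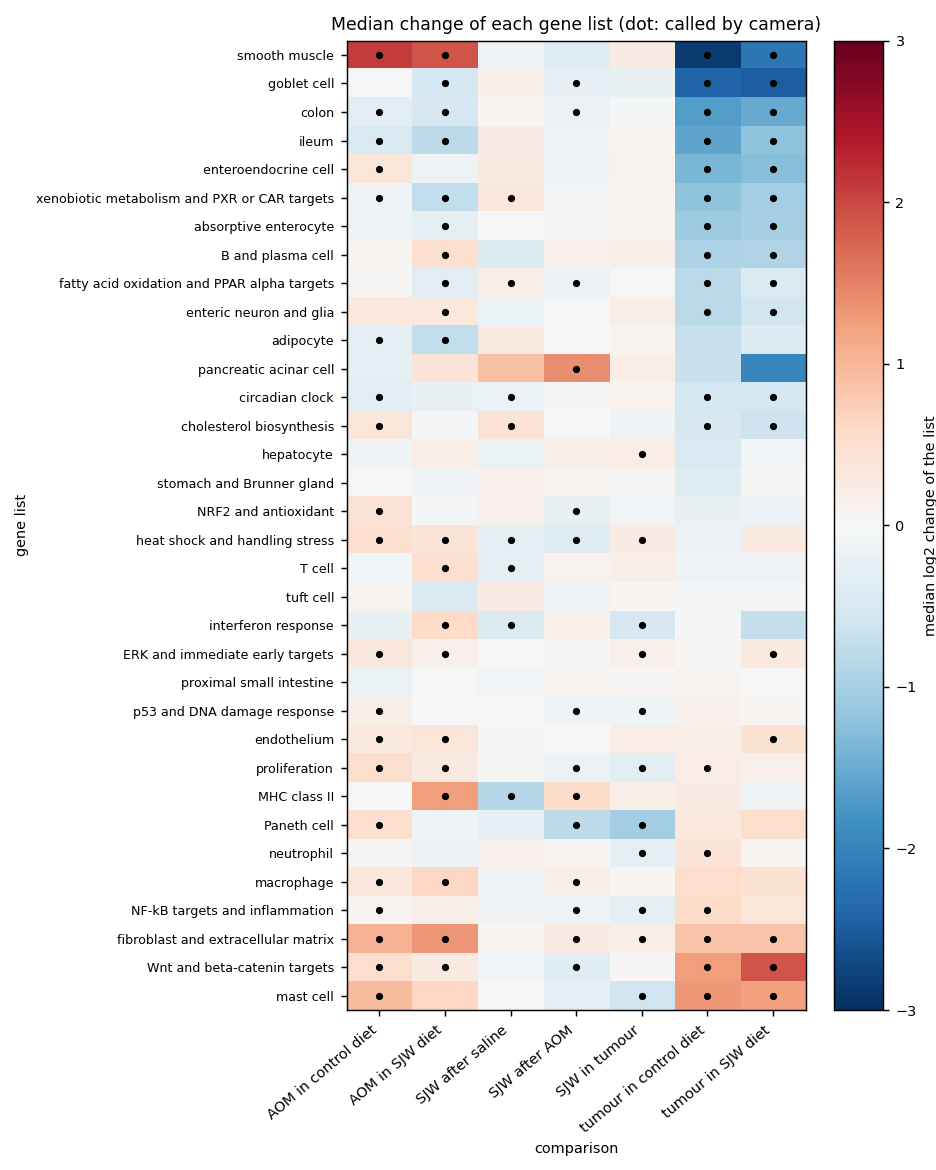
Median log2 change of each gene list (vertical axis) in 7 comparisons (horizontal axis), in colour from lower (blue) to higher (red); a dot marks a list called by the set test. Smooth muscle genes were at 2.09 and 1.90 after AOM and at -2.86 and -2.17 in tumours. The AOM non-tumour arrays enter both kinds of comparison with opposite sign, so these values are not independent.

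Tumours were compared with non-tumour tissue of AOM-treated mice on the same diet. These non-tumour arrays also enter the AOM comparison of that diet. Opposite changes after AOM and in tumours, as of smooth muscle genes, are therefore not independent. On the control diet, tumours had lower transcripts of the carbonic anhydrase gene Car4 (-6.01 ± 0.40), the water channel gene Aqp8 (-5.72 ± 0.46) and the chloride exchanger gene Slc26a3 (-5.52 ± 0.38), and of Hao2 (-4.91 ± 0.44). The goblet cell list members Clca1, Klk1 and Zg16 were lower, at -5.01 ± 0.62, -4.91 ± 0.49 and -4.70 ± 0.47. The matrix metalloprotease genes Mmp13 and Mmp10 rose by 3.37 ± 0.33 and 3.36 ± 0.27, the autophagy gene Atg9b by 3.35 ± 0.35 and Lcn2, an iron-binding innate immune protein gene, by 3.21 ± 0.64. In all, 3310 genes were higher and 5026 lower.

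Of 26 Wnt and beta-catenin targets 21 rose in these tumours and 0 fell (23 higher adjusted over the list alone; adjusted p = 0.0795 with an estimated correlation), with Sp5 at 2.51 ± 0.32, Notum at 2.48 ± 0.38, Axin2 at 1.78 ± 0.28 and the stem cell marker gene Lgr5 2.83-fold higher (log2 SE 0.36). Of 28 proliferation genes 9 rose (10 adjusted over the list alone; adjusted p = 0.407 with an estimated correlation), Top2a by 1.14 ± 0.21. NF-kB and inflammation genes rose in 14 and fell in 6 of 33 members (17 and 6 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation). Among them Il1b was at 1.94 ± 0.35, Tnf at 1.01 ± 0.29 and the metalloprotease gene Mmp9 at 2.37 ± 0.31. Il6 was not well above background in the non-tumour group and at least 1.64-fold higher in tumours (adjusted p = 4.13e-05). Such bounds rest on ratios without a dye swap and are open to dye bias. Myc rose 2.15-fold (log2 SE 0.27).

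Goblet cell genes fell in 13 of 15 members, and also in 13 adjusted over the list alone (adjusted p = 0.23 with an estimated correlation). Enteroendocrine genes fell in 15 of 20 (16 adjusted over the list alone; adjusted p = 0.0795 with an estimated correlation), with the proglucagon gene Gcg at -3.87 ± 0.35 and Chgb at -3.58 ± 0.35. Smooth muscle genes fell in 11 of 13 members, over all genes and adjusted over the list alone, with Des at -5.04 ± 0.81 and Cnn1 at -4.65 ± 0.85 (adjusted p = 0.387 for the list with an estimated correlation). Absorptive enterocyte genes fell in 16 and rose in 1 of 25, with Mep1b at -3.18 ± 0.35 (adjusted p = 0.162 for the list with an estimated correlation). Xenobiotic metabolism genes fell in 21 and rose in 3 of 34 (23 and 3 adjusted over the list alone), with Ces2c at -4.48 ± 0.36 (adjusted p = 0.196 for the list with an estimated correlation).

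Matrix genes rose in 13 and fell in 1 of 20 members (14 and 1 adjusted over the list alone; adjusted p = 0.336 with an estimated correlation), with Col5a2 at 2.02 ± 0.31. Mast cell markers rose in 7 of 9, and also in 7 adjusted over the list alone, and neutrophil markers in 4 of 11, with S100a8 at 2.28 ± 0.66 (adjusted p = 0.336 and 0.162 for these lists with an estimated correlation). Fatty acid oxidation, cholesterol biosynthesis, circadian clock, ileum, colon, B and plasma cell and enteric neuron lists were lower, at medians of -0.81, -0.48, -0.53, -1.59, -1.67, -0.93 and -0.80. Dbp fell by 1.47 ± 0.19. On leaving out 1 array, 4 of the called lists lost the call or moved by over 1.5 times, among them proliferation (0.12) and enteric neuron genes (-0.505) without control tumour replicate 3 and ileum genes (-1.02) without control AOM replicate 3. Of 34 lists 18 were called, 6 higher and 12 lower, and 0 held with an estimated correlation, at adjusted p of 0.0795 to 0.531.

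On the SJW diet 2398 genes were higher in tumours and 4017 lower. The metallothionein genes Mt4 and Mt3 rose by 4.50 ± 0.70 and 3.72 ± 0.44, and the Wnt targets Wif1, Notum, Sp5, Mmp7 and Nkd1 rose by 4.26 ± 0.58, 3.99 ± 0.38, 3.83 ± 0.32, 3.76 ± 0.54 and 3.72 ± 0.29. The keratin gene Krt23 rose by 3.92 ± 0.41. Car4 fell by 4.90 ± 0.40, Klk1 fell by 4.64 ± 0.49 and Cyp2c55 fell by 4.51 ± 0.48. Lgr5, Axin2, Lcn2, Il1b and Myc rose by 2.71 ± 0.36, 2.57 ± 0.28, 2.04 ± 0.64, 1.02 ± 0.35 and 0.84 ± 0.27, and Fos fell by 1.11 ± 0.37.

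Wnt and beta-catenin targets rose in 24 of 26 members, and in 24 adjusted over the list alone, with a median of 1.89 (adjusted p = 0.0271 with an estimated correlation). This was the only list call of the comparison that held. Goblet cell genes fell in 14 of 15 members, over all genes and adjusted over the list alone, with a median of -2.48 (adjusted p = 0.188 with an estimated correlation). Enteroendocrine genes fell in 10 of 20 (14 adjusted over the list alone) and smooth muscle genes in 9 of 13 (11 adjusted over the list alone), with adjusted p = 0.113 and 0.518 with an estimated correlation. ERK targets rose in 10 and fell in 3 of 25 (11 and 3 adjusted over the list alone), with Etv5 at 3.03 ± 0.37 (adjusted p = 0.113 for the list with an estimated correlation). Xenobiotic genes fell in 18 and rose in 2 of 34 (21 and 3 adjusted over the list alone; adjusted p = 0.188 with an estimated correlation). Cholesterol biosynthesis genes fell in 11 of 20, over all genes and adjusted over the list alone (adjusted p = 0.518 with an estimated correlation). Mast cell, matrix and endothelial lists were higher at medians of 1.24, 0.87 and 0.45. Colon, ileum, enterocyte, B and plasma cell, enteric neuron, circadian clock and fatty acid oxidation lists were lower at -1.502, -1.21, -0.99, -0.90, -0.60, -0.54 and -0.43. Of 34 lists 17 were called, 5 higher and 12 lower. Of these, 6 lost the call or moved by over 1.5 times on leaving out 1 array; without SJW AOM replicate 2 the smooth muscle median was -1.44 and the endothelial 0.16. Adjusted p of the other 16 was 0.106 to 0.531 with an estimated correlation.

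Of the tumour genes, 1694 were higher in both diets, where independent lists would share 304.4, and 3309 were lower in both against 774.3; 1 was called in opposite directions. These comparisons share no arrays, but they share the slides, the scan days and 1 fit, so their lists are not independent. The test of a difference between the diets in the tumour change called 0 genes by limma (1081, or 4.1%, at an unadjusted p under 0.05). Mt3 was at 2.80 ± 0.62 and the chemokine gene Cxcl3 at -1.32 ± 0.26 in it, with an adjusted p of 1. It called 1 gene without SJW tumour replicate 2.

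Tumour arrays lay on other slides, scanned on another day, than all non-tumour arrays, so that tumour and scan day cannot be told apart. With slide as a random block (consensus correlation -0.027) 8391 and 6470 genes passed on the control and SJW diets. As no slide held both tumour and non-tumour arrays, that block cannot test whether slides contribute to these calls. The balance of the calls depended on the scaling. On the control diet median centring gave 3777 higher and 1854 lower genes, the red channel alone 3759 and 3895, and the deposited values 3854 and 2646. On the SJW diet these gave 2703 and 1282, 3944 and 4055, and 2699 and 2515. Of the 8336 genes called on the control diet, 4108, 5227 and 4376 also passed with these settings in turn. Of the 6415 called on the SJW diet, 2953, 4408 and 3452 did. The median change of all genes moved to 0.11 with median centring and to 0.15 with the deposited table in the control diet tumours, from -0.06. It was -0.12 and -0.13 for AOM on the control and SJW diets with that table.

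**Figure D2:**
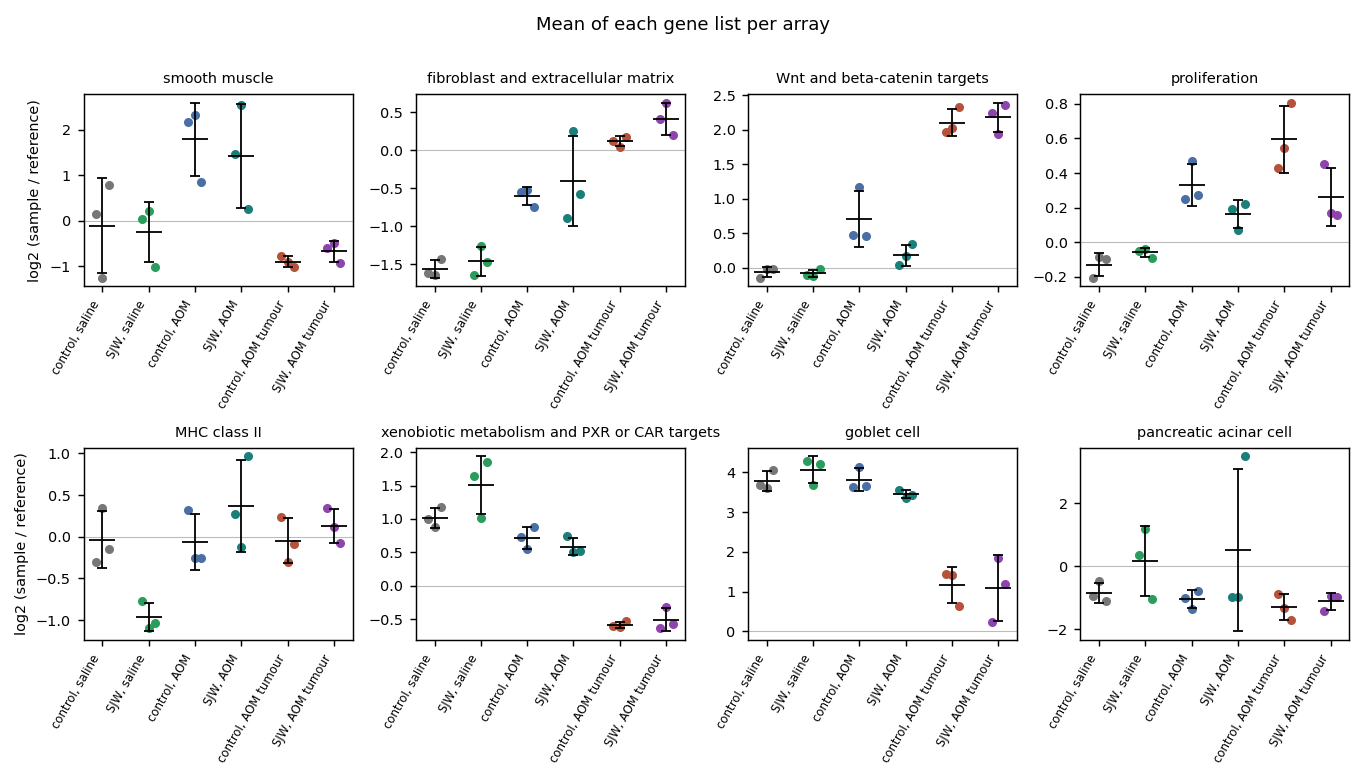
Mean log2 ratio (sample over reference, vertical axis) of 8 gene lists on each array, by group; points are arrays, and lines with bars are the mean and SD of 3 arrays. Pancreatic acinar genes were at 3.49 in SJW AOM replicate 3 and between -1.69 and 1.18 on the other arrays.

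**Figure D3:**
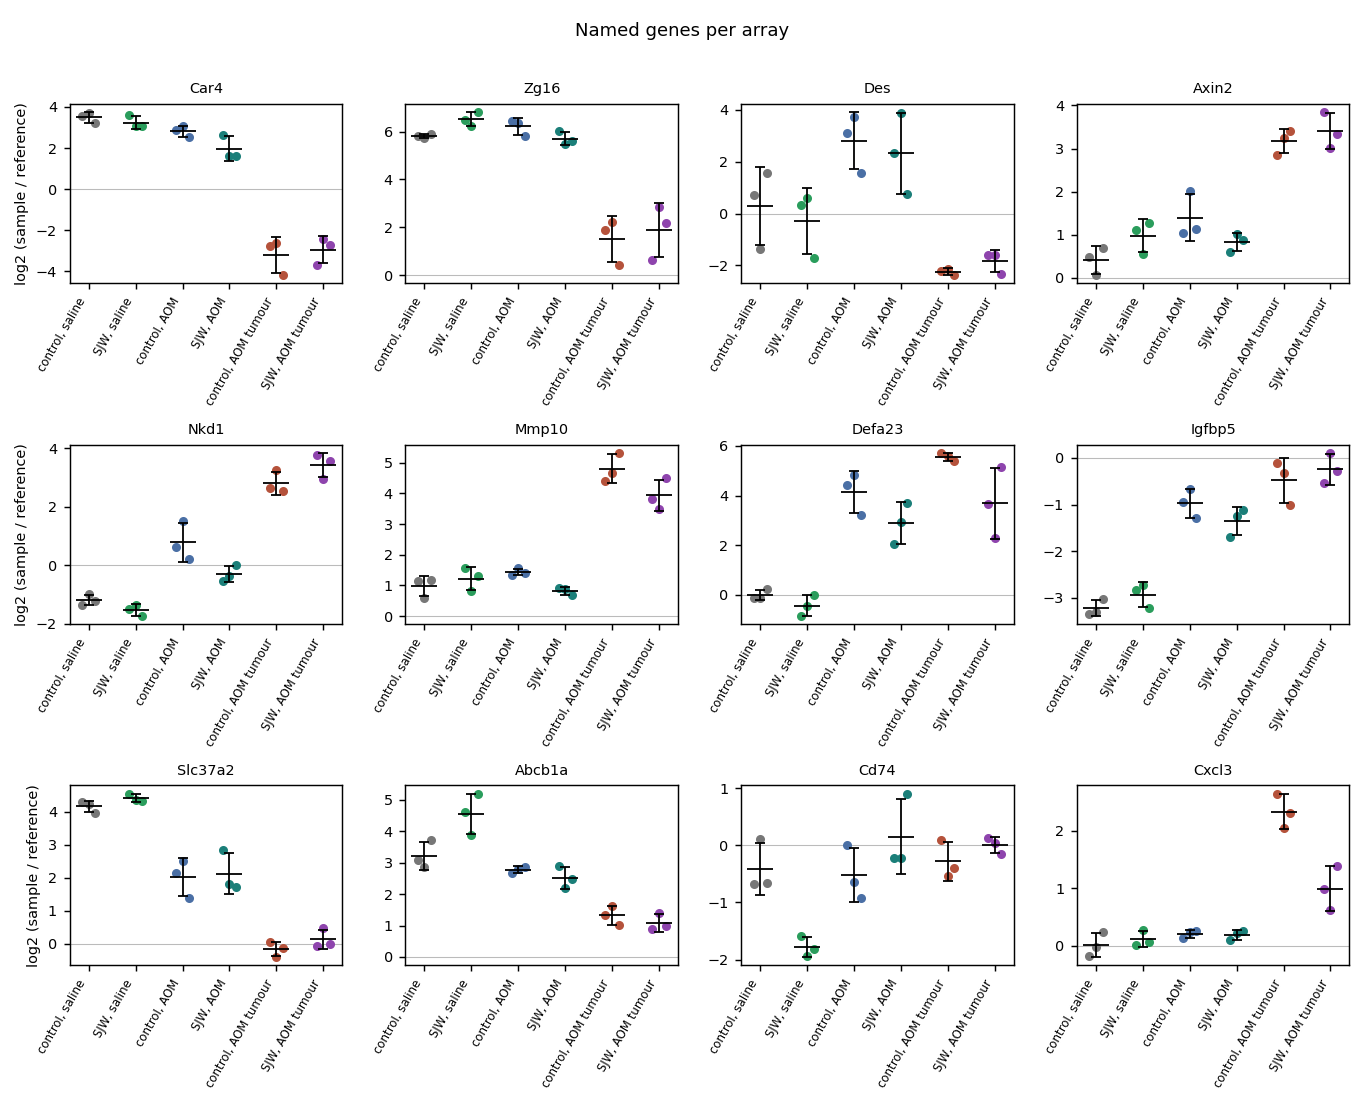
Log2 ratio (sample over reference, vertical axis) of 12 genes on each array, by group; points are arrays, and lines with bars are the mean and SD of 3 arrays. Car4 was at 2.82 ± 0.27 (SD, n = 3) in non-tumour tissue of AOM-treated control diet mice and -3.19 ± 0.87 in their tumours.

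The SJW diet was compared with the control diet after saline, after AOM and in tumours. After saline 0 genes passed by limma (2789, or 10.7%, at an unadjusted p under 0.05, smallest adjusted p 0.0837). The aldo-keto reductase genes Akr1b7 and Akr1b8 were at 1.16 ± 0.19 and 1.02 ± 0.16, and the monooxygenase gene Fmo9 was at 1.18 ± 0.20. Olfr141, an olfactory receptor gene, was at 1.25 ± 0.18 and Pirt at 1.42 ± 0.24. Lower values included Tppp3 at -1.28 ± 0.25, Cd74 at -1.36 ± 0.31 and H2-Aa at -1.57 ± 0.37.

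Xenobiotic metabolism and PXR or CAR target genes were higher in 27 of 34 members on SJW after saline, with a median of 0.33 (adjusted p = 0.584 with an estimated correlation). The nuclear receptor PXR is known to be activated by hyperforin, a constituent of the herb. Over all genes 0 passed, and 9 were higher adjusted over the list alone, among them Abcb1a at 1.33 ± 0.29 and Cyp3a41a at 0.71 ± 0.13; Cyp3a11 was at 0.02 ± 0.26. All 7 MHC class II genes had negative changes, with a median of -0.85 (0 called, 6 lower adjusted over the list alone; adjusted p = 0.378 with an estimated correlation). Cholesterol biosynthesis genes were positive in all 20 members, with a median of 0.44 (0 called, 3 adjusted over the list alone; adjusted p = 0.769 with an estimated correlation). Interferon response genes were negative in all 18 (median -0.43), with 0 called over all genes or adjusted over the list alone (adjusted p = 0.869 with an estimated correlation). T cell and circadian clock genes were lower (medians -0.30 and -0.19), with 2 members each adjusted over the list alone and adjusted p = 0.584 and 0.311 with an estimated correlation. Fatty acid oxidation genes were higher and heat shock genes lower, at medians of 0.19 and -0.29; the first was -0.05 without the arrays of bright reference, with 1 array left in each group. With median centring the clock and heat shock medians were 0.13 and 0.07. Of 34 lists 8 were called, 3 higher and 5 lower, all 8 also with slide as a block; 0 held with an estimated correlation, at adjusted p of 0.311 to 0.869.

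Within slides the median of the xenobiotic list was 0.09 to 0.47, that of MHC class II -1.49 to -0.59, that of fatty acid oxidation genes -0.04 to 0.42 and that of interferon genes -1.13 to 0.62. Leaving out 1 array ended the call or moved the median by over 1.5 times for 7 of the 8 lists. Xenobiotic genes were at 0.18 and interferon genes at -1.13 without SJW saline replicate 3. Without replicate 2 xenobiotic and cholesterol genes were at 0.57 and 0.24, and without replicate 1 interferon genes were at -0.05. Pancreatic acinar genes, not called here, had means of 0.38, 1.18 and -1.025 in SJW saline replicates 1 to 3. In control saline these were -0.95, -0.48 and -1.11. With slide as a block 71 genes passed after saline, 69 higher and 2 lower, including Akr1b7, Akr1b8 and Fmo9, against 0 with the replicate number, which the tumour arrays share, as a block. The count was 291 without control saline replicate 3, 203 without SJW saline replicate 1 and 412 with array weights; 4 lists were called without control saline replicate 3. The SJW saline arrays enter both this comparison and that of AOM on the SJW diet, so the opposite values of Cd74, H2-Aa, Abcb1a and Akr1b7 in the 2 comparisons are not independent.

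After AOM 0 genes passed between the diets by limma (adjusted p of 0.999 or more), and also 0 with slide as a block. At an unadjusted p under 0.05 there were 831 (3.2% of genes), fewer than without any difference. Sprr2h was at -2.04 ± 0.45, Krt23 at -1.79 ± 0.41 and Gda at -0.86 ± 0.19, while Myoz1 was at 0.97 ± 0.23. Wnt and beta-catenin targets were lower on SJW in 23 of 26 members (median -0.36; 0 called, 3 lower adjusted over the list alone; adjusted p = 0.231 with an estimated correlation), with Nkd1 at -1.08 ± 0.29 and Wif1 at -1.95 ± 0.58. The Wnt median was -0.75 to -0.18 within slides and -0.21 without control AOM replicate 2. Proliferation genes were lower in 23 of 28 (median -0.18) and NRF2 genes in 15 of 17 (median -0.22; 1 lower adjusted over the list alone), with adjusted p = 0.428 and 0.144 with an estimated correlation. MHC class II genes were positive in all 7 (median 0.54) and Paneth cell genes were lower (median -0.77), with 0 called over all genes or adjusted over the list alone (adjusted p = 0.428 for both with an estimated correlation). NF-kB, p53, fatty acid oxidation, heat shock, colon and goblet lists were lower at medians of -0.12, -0.12, -0.18, -0.38, -0.17 and -0.25, and macrophage and matrix lists higher at 0.20 and 0.25. The colon median was 0.09 with the scanner's own log ratio, 0.115 with the deposited table and 0.003 with the red channel alone. The medians of 8 of the called lists turned between slides: MHC class II (-0.20 to 1.12), Paneth cell (-1.61 to 0.16), NF-kB (-0.435 to 0.09), p53 (-0.26 to 0.05), fatty acid oxidation (-0.29 to 0.045), colon (-0.58 to 0.16), macrophage (-0.29 to 0.72) and matrix genes (-0.36 to 0.92). All 14 called lists lost the call or moved by over 1.5 times on leaving out 1 array. MHC class II, macrophage and colon genes were at 0.18, -0.10 and -0.02 without SJW AOM replicate 3, matrix genes at -0.04 without replicate 2, and Paneth cell, heat shock and p53 genes at -0.33, -0.18 and -0.01 without control AOM replicate 2. Of 34 lists 14 were called, 4 higher and 10 lower (9 without SJW AOM replicate 3), all 14 with slide as a block and 13 with reference brightness as a block (p53 at adjusted p = 0.241); 0 held with an estimated correlation, at adjusted p of 0.144 to 0.581.

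Pancreatic acinar genes were higher on SJW after AOM, with a median of 1.39 and all 14 members positive (0 called, 0 adjusted over the list alone; adjusted p = 0.428 with an estimated correlation). Their mean was 3.49 in SJW AOM replicate 3, against -0.98 and -0.96 in the other replicates of that group. The median was 0.10 without that array (adjusted p = 0.378) and 2.17 and 2.21 without replicates 1 and 2.

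In tumours 0 genes passed between the diets (1558, or 6%, at an unadjusted p under 0.05) and 0 with slide as a block. The chemokine gene Cxcl3 was at -1.33 ± 0.18 on SJW (adjusted p = 0.0557), the complement gene Cfb at -1.18 ± 0.18, the NADPH oxidase organiser gene Noxo1 at -1.04 ± 0.16 and Il6 at -0.79 ± 0.15. Ddah2 was at 0.79 ± 0.15 and Tsc22d1 at 0.92 ± 0.18. NF-kB and inflammation genes were lower on SJW in 25 of 33 members, with a median of -0.27 (0 called, 4 lower adjusted over the list alone; adjusted p = 0.0736 with an estimated correlation), including Ccl20 at -1.24 ± 0.33 and Icam1 at -0.73 ± 0.22. All 28 proliferation genes were lower (median -0.32; 0 called, 3 adjusted over the list alone; adjusted p = 0.102 with an estimated correlation), with Top2a at -0.87 ± 0.21. Paneth cell genes had a median of -1.05 (0 called, 3 lower adjusted over the list alone) and neutrophil genes of -0.27 (0 called, 1 adjusted over the list alone). With an estimated correlation, adjusted p was 0.0736 for neutrophil and 0.298 for Paneth cell genes.

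Within the first and second tumour slide the median of inflammation genes was -0.42 and -0.08, and that of proliferation genes -0.15 and -0.67. Interferon (-0.74 and 0.02), neutrophil (-0.40 and 0.07) and matrix genes (0.41 and -0.005) turned between these slides. Interferon response and mast cell genes were also lower, at medians of -0.50 and -0.59, with p53 genes at -0.13. ERK, heat shock, matrix and hepatocyte lists were higher, at 0.15, 0.26, 0.20 and 0.22. Of 34 lists 11 were called, 4 higher and 7 lower, all 11 with slide as a block and 9 with reference brightness as a block (adjusted p of 0.139 for p53 and 0.0985 for mast cell genes); 0 held with an estimated correlation, at adjusted p of 0.0736 to 0.853. The count of genes was 8 without control tumour replicate 1, 6 without SJW tumour replicate 3, 3 without control tumour replicate 2, and 1 without control tumour replicate 3 or SJW tumour replicate 2. Without control tumour replicate 3, 6 lists were called, with Paneth cell genes at -0.45 and mast cell genes at 0.03. Of the 11 lists 9 lost the call or moved by over 1.5 times on leaving out 1 array.

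In the SJW change averaged over saline, AOM and tumour, 0 genes passed by limma. At an unadjusted p under 0.05 there were 1317 (5.1% of genes), about as many as without any difference. The count that passed was 11 without SJW saline replicate 1 and 1 without control tumour replicate 2. Cfb was at -0.55 ± 0.10 and Sprr2h at -1.26 ± 0.26 (adjusted p = 0.976 for both). NF-kB and inflammation genes were lower in 29 of 33 members (median -0.20; 0 called, 5 lower adjusted over the list alone; adjusted p = 0.0803 with an estimated correlation). Paneth cell genes had a median of -0.86 and xenobiotic genes 0.14 (0.01 without the arrays of bright reference, 0.06 without SJW saline replicate 3), with 3 lower and 4 higher members adjusted over the list alone (adjusted p = 0.232 and 0.527 with an estimated correlation). Acinar, matrix and cholesterol lists were higher at medians of 0.77, 0.18 and 0.11, the first at 0.30 without SJW AOM replicate 3. Proliferation, interferon, Wnt, p53, NRF2, heat shock and mast cell lists were lower at -0.14, -0.27, -0.11, -0.07, -0.01, -0.15 and -0.27. With median centring p53 and NRF2 genes were at 0.01 and 0.07, and Wnt targets were at 0.02 with the red channel alone. Of 34 lists 13 were called, 4 higher and 9 lower (7 without control AOM replicate 2, and 8 held with reference brightness as a block). Of these, 11 lost the call or moved by over 1.5 times on leaving out 1 array, and 0 held with an estimated correlation, at adjusted p of 0.0803 to 0.739.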

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

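Of the tests in this part, that with reference brightness as a block was chosen after the result was seen. The gene lists below were called in the tests of a difference between diets, in which limma called 0 single genes. With an estimated correlation 0 of these calls held (adjusted p of 0.348 to 0.712 for AOM and 0.28 to 0.733 for tumours).

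The change after AOM differed between the diets for 12 lists. The median difference, SJW minus control diet, was 1.22 for MHC class II genes (5 of 7 members higher adjusted over the list alone), 0.568 for interferon response genes, 0.482 for T cell and 0.229 for macrophage genes. It was -0.452 for xenobiotic metabolism, -0.405 for fatty acid oxidation, -0.457 for cholesterol biosynthesis, -0.465 for Wnt targets, -0.397 for NRF2 genes, -0.257 for proliferation, -0.506 for goblet cell and -0.445 for enteroendocrine genes. On leaving out 1 array 8 of these lists lost the call, and interferon genes were at 0.215 without SJW saline replicate 1 and 1.328 without replicate 3. Without control saline replicate 3, 5 lists were called.

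The change from non-tumour tissue to tumour differed between the diets for 11 lists. The median difference, SJW minus control diet, was 0.653 for heat shock genes, 0.43 for Wnt targets, 0.337 for enteroendocrine genes, 0.249 for fatty acid oxidation, 0.169 for xenobiotic metabolism and 0.166 for ERK targets. It was -1.497 for pancreatic acinar genes, -0.672 for interferon response, -0.326 for neutrophil, -0.221 for NF-kB and -0.143 for proliferation genes. The acinar value was 0.074 without SJW AOM replicate 3 (adjusted p = 0.785), and -2.257 and -2.325 without replicates 1 and 2 of that group. On leaving out 1 array 10 of the 11 lists lost the call or moved by over 1.5 times, and 9 calls held with reference brightness as a block. Without SJW tumour replicate 2, 5 lists were called, and 7 without SJW AOM replicate 3 or control tumour replicate 1.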

How the results depend on the processing

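Tests chosen after the result was seen were those without non-uniform spots, with the brightness of the reference channel, and with slide as a block for lists. The AOM counts of 151 and 295 moved by over 1.5 times under many settings. Array signal over background limits dim genes. Where a value moved, the cause was not tested, except that non-uniform spots left 16487 genes to test.

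In the order AOM on the control diet and AOM on SJW, the count was 564 and 116 with the software's log ratio, 280 and 139 with median centring (3985 for tumours on SJW) and 335 and 66 with the deposited table. It was 996 and 1709 with array weights, which also gave 412 for SJW after saline, 2 for SJW in tumours and 10240 for tumours on SJW. With only the groups compared, 7 and 0 genes passed, and 5496 for tumours on the control diet. Without non-uniform spots 19 and 64 passed, 4265 and 3025 for tumours and 1 for SJW in tumours; the same genes with those spots kept gave 21, 65, 4381, 3139 and 1. Reference brightness as a block gave 267 and 7, and leaving out the 6 bright arrays 0 and 0, with 15 for SJW after saline; this left 1 saline array on each diet, so that it says little about brightness. Both channels above background gave 287 for AOM on the control diet, and the red channel alone 8 for AOM on SJW and 1 for SJW in tumours. SJW after saline had 2 genes with the software's log ratio, 2 with the deposited table, 71 with slide as a block and 1 with a trended, robust variance, which also gave 1 for SJW in tumours.

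Lists called for SJW after saline were 15 with the software's log ratio, 14 with the deposited table and 16 with the red channel alone, and for SJW after AOM 9 and 8 with the first 2. For the tumour difference between diets they were 6, 6 and, with both channels above background, 7, as for SJW in tumours. The SJW average had 8 with reference brightness as a block, and the AOM difference between diets 6 without the bright arrays. With an estimated correlation 2 lists were called for AOM on the control diet, 1 for tumours on SJW and 0 in each other comparison. Fry called 7 and 9 for AOM and 0 for the SJW comparisons, their average and both differences.

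Directions turned as follows. Without the bright arrays, the median was 0.115 for adipocyte genes (AOM, control diet), -0.053 for fatty acid oxidation (SJW after saline) and 0.06 for mast cell genes (SJW average). Adipoq was then at 0.211, Cidec at 0.103 and Cpa3 at 0.078. For xenobiotic genes in the SJW average only the set test turned, while the median stayed positive (0.142 with all arrays, 0.009 without the bright ones). For SJW after AOM, leaving out 1 array gave matrix genes -0.041 (without SJW AOM replicate 2) to 0.508 and macrophage genes -0.095 (without replicate 3) to 0.366, and Slc26a3 at 0.155 and 0.121 with the software's log ratio and the deposited table. Other genes were Ms4a2 at -0.011 (software's log ratio), Dnajb1 at 0.043 and Ctss at -0.281 (median centring), Chordc1 at -0.113 and Tef at 0.201 (deposited table), Bcas1 at 0.117 and Tnfaip3 at 0.046 (red alone), Csf1r at -0.12 (without non-uniform spots) and Ccne1 at 0.079 (mean of probes). Over all alternatives but Aquantile 11034 values of named genes kept direction and side of the threshold, 607 lost it, 167 gained it and 14 turned; for lists 2134 kept it, 597 lost it and 6 turned in the set test. In 15 more cases only the median changed sign. Without the bright arrays this was so for enterocyte (0.07) and ileum genes (0.147) in AOM on SJW, mast cell genes (0.028) for SJW in tumours and Wnt targets (0.003) in the SJW average. With median centring it was so for clock (0.132) and heat shock genes (0.066) after saline and p53 (0.01) and NRF2 genes (0.071) in the average. Colon genes for SJW after AOM were at 0.087 with the software's log ratio, 0.115 with the deposited table and 0.003 with red alone, and Wnt targets in the average at 0.019 with red alone. Mast cell genes in tumours were at 0.028 without control tumour replicate 3, acinar genes in the tumour difference at 0.074 without SJW AOM replicate 3, and NRF2 genes in the average at 0.004 without control saline replicate 2.

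Leaving out 1 array of the groups compared gave 11 to 193 and 0 to 600 genes for AOM, 0 to 291, 0 to 0 and 0 to 8 for SJW after saline, after AOM and in tumours, 6159 to 7603 and 4477 to 5381 for tumours, 0 to 11 for the SJW average, and 0 to 2 and 0 to 1 for the differences. For lists in this order the ranges were 13 to 20, 18 to 20, 4 to 11, 9 to 15, 6 to 13, 16 to 20, 13 to 19, 7 to 16, 5 to 13 and 5 to 15. A group left with fewer arrays shares the spread of the others.

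With the replicate number as a block, 133 and 295 genes passed for AOM, 6279 and 4641 for tumours and 0 in each other comparison, and the block changed no other call of a count. Correlations of same-numbered arrays were -0.348 to 0.055 and 0.025 to 0.3 for AOM, -0.006 to 0.144 for SJW after AOM, -0.16 to 0.137 in tumours, and -0.329 to 0.318 and -0.07 to 0.072 for tumours against non-tumour tissue. Same-numbered non-tumour arrays share a slide, which was also run as a block. Aquantile changes no ratio and tests nothing here. Scan day was not run as a block, since the groups fix it.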

Other observations

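Tests chosen after the result was seen were those of the brightness of the reference channel, of markers of gut position and of handling by scan day. Proximal small intestine, stomach and Brunner gland, and tuft cell lists were called in 0 of 10 comparisons, with medians of -0.192 to 0.129, -0.352 to 0.132 and -0.434 to 0.244 and smallest adjusted p of 0.104, 0.7 and 0.154.

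In the 6 saline arrays, log2 ratios to the reference were 7.92 for the carbonic anhydrase gene Car1, 6.95 for Slc26a3, 4.18 for Aqp8 and 3.37 for Car4, all in the colon list. They were 0.03 for the lactase gene Lct and -1.36 for Fabp1, 1.77 for the ileal bile acid binding protein gene Fabp6 and -3.22 for the liver gene Alb. Hepatocyte markers had a median of -1.095, and their median lay below 0 on each array (single markers Tat and Cyp7a1 were at 0.78 and 0.65), which argues against liver RNA as the extraction label has it. The pool holds no gut, so genes abundant in small intestine would lie far above 0. The 5 alpha-defensin genes in the Paneth cell list had means of -0.385 to 0.075 (0.536 at most with 2 SD added; 3 of the 5 were well above background on each array) and Alpi was at 0.01 (Defa39, outside the list, at 0.67 on the control diet and 1.52 on SJW), while Defa22 and Defa23 rose after AOM by the same probes, which argues against small intestine, as the labels have it, as the whole source. Other Paneth list members went both ways: Mptx1 was at 5.67 and Itln1 at 3.64, but Lyz1 at -2.85 and Habp2 at -0.91. A part from small intestine therefore stays open. A colon origin stays open too: 13 of 16 colon markers were above 1, but proximal small intestine markers went both ways, from -1.36 to 2.73 with a median of 0.03.

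The AOM calls in non-tumour tissue may in part follow the reference channel or the amount of muscle layer in the samples. With reference brightness as a block the genes called on the control diet kept 99.3% of their median size and 267 passed, which argues against brightness as the whole cause. On SJW they kept 99% (1.008 before, 0.997 after, SD 0.476), but the median SE went from 0.205 to 0.226 and 7 passed, which leaves it open. The reference channel alone gave 3.5% and 8.1% of the median size on the control and SJW diets, with 0 genes called in that channel. On SJW its median part was 0.071 (SD 0.212), beside 0.835 (SD 0.528) from the sample channel. With the mean of the smooth muscle list as a covariate the sizes kept were 91.4% (0.975 before, 0.891 after, SD 0.787) and 98.1% (0.988 after, SD 0.522), the SE went to 0.223 and 0.249, and 0 and 28 genes passed. Muscle layer, and an effect of AOM itself, therefore stay open for both diets.

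The tumour calls could come from the scan day, on which tumour and non-tumour arrays part. The reference channel alone gave -0.2% and -2.8% of the median size of the called changes on the control and SJW diets (median parts of -0.001 and -0.021, SD 0.377 and 0.409, beside 0.686 and 0.75 from the sample channel), which argues against a shift of that channel as the whole cause. The channel itself differed at 2315 and 3398 genes between tumour and non-tumour arrays, so that a part from it stays open. Any other difference between the days, such as handling of the sample RNA, which no header used here records, cannot be told apart from tumour, since 0% of the tumour arrays on either diet share a scan day with a non-tumour array. The difference between tumour and normal tissue that the design names stays open and untested.

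Other splits of the same arrays were counted. For AOM, 1 of 10 splits, the real one, called 151 genes on the control diet (highest other 9) and 1 of 10 called 295 on SJW (highest other 10). For tumours it was 1 of 10 in each diet, with 8336 and 6415 genes and a highest other of 0. Each of these has too few splits for a share under 0.05. The other real counts were 0, which any split equals or exceeds, so their splits test nothing. These were all 10 splits for SJW after saline, after AOM and in tumours (highest others 90, 1 and 1), and 100 of 100 drawn splits for the SJW average and the AOM and tumour differences between diets (highest others 13, 44 and 1). The split with 90 genes set 3 of the 4 saline arrays of bright reference against the other 3 saline arrays, which held the remaining bright one. It was picked as the highest of 10, so it does not test an effect of brightness. With brightness as a block 0 genes passed for SJW after saline, and 71 with slide as a block.

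Pancreatic acinar genes had a mean log2 ratio of 3.49 in SJW AOM replicate 3, 1.18 in SJW saline replicate 2 and 0.38 in SJW saline replicate 1. They lay between -1.69 and -0.48 on the other 15 arrays.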
